A study of Mus musculus with 2 samples.

How the data were processed

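Single-cell RNA sequencing was done on 2 libraries of dissociated mouse skin tumours, 1 from control mice (Ctrl-D) and 1 from mice with an inducible deletion of Eed in keratin 14-expressing cells (Eed iKO-D). Per the labels' protocols, chopped tumours were digested with collagenase, DNase and trypsin, strained, and passed through a dead cell removal kit, and libraries were made with the 10x Genomics Chromium 3' kit, version 2. Tamoxifen was given from postnatal day 50 on 4 days, and DMBA weekly for up to 20 weeks. The authors deposited whole-number UMI counts per gene and barcode for 32285 genes, as matrices limited to barcodes called as cells. The sources differ on the version of Cell Ranger, the program that aligns reads and counts UMIs. It is 2.1.0 per the labels' extract protocol, 7.1.0 per the file headers and 8.0 per the submitters' processing notes. The genome build was mm10 per the submitters' processing notes. Coordinates came from the mm10 annotation given for this work, in which 99.6% of the gene IDs were found.

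Cells were kept when they had at least 500 genes and at most 15% of UMIs from mitochondrial genes, which 93.6% of barcodes in Ctrl-D and 96.5% in Eed iKO-D met. Scrublet was run per library with an expected doublet rate of 0.08. It called 133 of 7522 cells in Ctrl-D, which were removed, and 0 of 21484 in Eed iKO-D, where it did not work, so doublets remain in that library. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 gave 30 clusters over both libraries. Batch correction was not applied.

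Clusters were called "X-like" from marker lists fixed before the data were examined. The scoring rule was set after the data were seen. A cluster needed a mean marker score of at least 0.5, a lead of at least 0.3 over the next lineage and at least 3 raised markers. Clusters with over 10% of UMIs from Gm42418 and fewer than 3 of their markers among their 10 leading genes stayed unnamed, as did a plasmacytoid cluster led by Siglech, and erythroid markers were not used. In all, 8 clusters were epithelial-like and 12 were unnamed, the latter with 647 Ctrl-D and 12608 Eed iKO-D cells.

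UMIs were summed per library and class and given as CPM, that is scaled to a common total per class. With 1 library per group there was no test. CPM values carry exact Poisson intervals, shares exact Clopper-Pearson intervals, and ratios exact conditional binomial intervals, all at 95%. A gene with 0 UMIs in a library was set against a floor of 3 UMIs over the class. Classes with at least 100 cells in each library were compared, which left 4 classes. For each of 41 gene lists fixed before the data were examined, the median log2 ratio was taken over members with at least 20 UMIs in both libraries together, with 0.5 UMI added to each count. Members at least 1.5 times apart were counted. The median's percentile was taken among 10000 random lists matched on mean expression, and its interval from 2000 resamples of the members. Cycling cells had over 1% of their UMIs in S or G2/M genes after thinning to 1500 UMIs.

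Genes named in the text were chosen by a rule written before the data were examined. In epithelial-like cells these were the 12 highest and 12 lowest log2 ratios after 5 CPM were added, and in the other classes the 4 highest and 4 lowest. Genes needed at least 50 UMIs and 50 CPM in the higher library. As a guard against free RNA, 3 times the CPM in the class had to reach the highest CPM of any other named class of that library. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor, clone-named and sex chromosome genes were left out. A few genes that the rule chose are not reported here. A fixed set that included Eed, other PRC2 genes, keratins, Cdkn2a and Vegfa was always named, with examples from each list that was described. The rule took the largest ratios of a list as its examples; other members named beside these, such as Ldha, Cd44, Itga6, B2m, Ereg, Inhba, Ptn, Flg, Ivl, Dusp6, Cxcl12, Slc2a1 and Foxp3, were chosen after their values were seen.

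The comparison of summed counts was tested on simulated data for the real genes and depths. Counts were drawn from 1 pooled profile per class, with no differences between cells, tumours, animals or libraries. The test therefore checks the calculation and counting error only, and unrelated differences between 2 real libraries can be larger. The intervals covered the true ratio for 95.9% of 19393 genes in epithelial-like cells, 96.4% of 16906 in fibroblast-like, 97.9% of 10718 in neutrophil-like and 96.0% of 9212 in T cell-like cells. Unchanged genes passed 1.5-fold by counting error alone in 3.87%, 21.1%, 41.1% and 9.39%. True 2-fold differences passed it in 92.9%, 90.8%, 72.8% and 88.7%, in the same order. Depth therefore limits neutrophil-like cells most.

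Alternatives covered the cell filter, doublets, clustering resolution, cell assignment, scaling, free RNA subtraction, weighting of cells, list filters and thinning. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9.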

Results

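Squamous tumours of the dorsal skin of 5-month-old mice were dissociated whole, and their cells were profiled by droplet-based single-cell RNA sequencing of the 3' ends of transcripts. The tumours had been induced with the carcinogen DMBA. One library came from Eed flox/flox mice that received the solvent ethanol, here called Ctrl-D. The other came from Eed flox/flox mice that carried a tamoxifen-inducible Cre recombinase under the keratin 14 promoter and received hydroxytamoxifen, here called Eed iKO-D. Eed is a core subunit of Polycomb repressive complex 2 (PRC2), which places the repressive mark H3K27me3. The series title names oncogenic Ras, loss of EED and the tumour niche, so the comparison asked how epithelial cells and their neighbours differed between tumours of both genotypes. Each group had 1 library, so no difference has a replicate check and no p-value was computed. Genotype and tamoxifen differed together. The number and sex of the animals per library were not given in the labels.

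The Ctrl-D library held 8039 barcodes with 120500892 UMIs (unique molecular identifiers, 1 per captured transcript), and the Eed iKO-D library held 22259 barcodes with 289511009 UMIs. The labels state a target of 8013 to 19511 cells. After filtering, 7389 and 21484 cells were kept, with medians of 13045 and 3191 UMIs per cell. Of these, 6742 and 8876 lay in clusters that could be given a cell class. The unnamed cells were 8.76% of the kept cells in Ctrl-D and 58.7% in Eed iKO-D, where their median was 2365 UMIs. Intervals given below are exact 95% intervals that cover counting error only.

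The target gene was examined first. In epithelial-like cells Eed (ENSMUSG00000030619, mm10 chromosome 7, 89954654 to 89980983, minus strand) had 5298 UMIs in Ctrl-D and 6613 in Eed iKO-D. This gave 52.9 (51.5 to 54.4) and 47.4 (46.3 to 48.5) CPM (UMIs scaled to a common total per class), a ratio of 0.896 (0.864 to 0.929). In fibroblast-like cells, which should lack the Cre, Eed stood at 27.1 CPM in Ctrl-D and 23.3 in Eed iKO-D. Reads from the 3' end may lie outside the deleted exons, which the labels do not name, so this level checks little about the deletion. Within the 5 epithelial-like clusters with at least 50 cells in each library, called shared clusters here, the median log2 ratio of Eed was 0.039. Among other PRC2 genes, the catalytic subunit Ezh2 stood at 83.7 CPM in Ctrl-D and 59.0 in Eed iKO-D (ratio 0.705), and Ezh1 at 11.2 and 11.9. Suz12, the third core subunit, was 1.73-fold higher in Eed iKO-D (68.4 against 118 CPM), but within shared clusters by 1.5-fold in only 2 of 5. The accessory subunits Jarid2 (201 against 706 CPM, 3.52-fold) and Aebp2 (76.1 against 157 CPM, 2.07-fold) were also higher. Jarid2 was higher in classes that should lack the Cre as well. It stood at 194 and 440 CPM in T cell-like cells. In fibroblast-like clusters 4 and 22 it stood at 51.7 and 101 CPM and at 59.1 and 127 CPM. Its rise was thus not limited to epithelial-like cells, although free RNA may contribute in the others. Of 11 PRC2 genes, 3 were at least 1.5 times higher and 1 at least 1.5 times lower, with a median log2 ratio of −0.01.

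Cell classes differed in share between the libraries. Epithelial-like cells made up 80.6% (79.7 to 81.6) of named cells in Ctrl-D and 35.4% (34.4 to 36.4) in Eed iKO-D. Fibroblast-like cells made up 3.68% and 27.5%, neutrophil-like cells 2.03% and 12.8%, and macrophage- or monocyte-like cells 1.10% and 10.5%. Blood endothelial-like cells stood at 0.282% and 6.14%, and pericyte- or smooth muscle-like cells at 0.534% and 4.86%. In the other direction, T cell-like cells made up 6.97% in Ctrl-D and 1.74% in Eed iKO-D, and melanocyte-like cells 3.68% and 0.0789%. Dendritic cell-like cells made up 0.816% and 0.158%, and mast cell-like cells 0.282% and 0.744%. These shares depended on dissociation, on dead cell removal, on the unnamed cells and on how cells were assigned. When each cell was assigned by its own marker UMIs, epithelial-like cells were 75.0% of the Eed iKO-D cells. Transcripts of other classes were found in every class: Krt14 in neutrophil-like cells was at 13.2% of its epithelial level in Ctrl-D and 23.6% in Eed iKO-D.

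**Figure D1:**
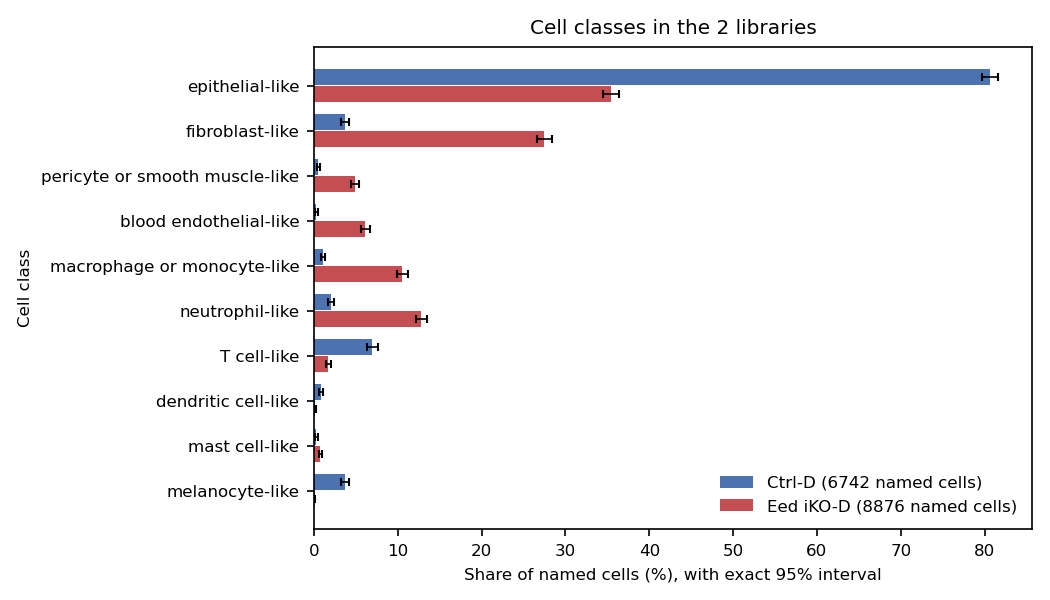
Share of named cells (%) per cell class in Ctrl-D (blue, 6742 named cells) and Eed iKO-D (red, 8876 named cells), with exact 95% intervals as error bars. Epithelial-like cells made up 80.6% and 35.4%, and fibroblast-like cells 3.68% and 27.5%.

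The epithelial comparison used 5436 Ctrl-D and 3145 Eed iKO-D cells, with medians of 15665 and 37690 UMIs. Most Ctrl-D cells lay in clusters 0, 8, 2 and 11, and most Eed iKO-D cells in clusters 7, 1, 6 and 25. Of the main clusters, 8, 7, 6 and 25 were called basal-like and 0, 2, 11 and 1 suprabasal-like. A cluster was called suprabasal-like whenever its basal markers did not score highest. Cluster 2 got this name although Krt10 stood at 106 CPM there, against 4334 CPM in Ctrl-D cells of cluster 11, and Vim at 635 CPM. Values for suprabasal-like clusters alone include its 632 Ctrl-D cells. The median log2 ratio of all genes was 0.34, so Eed iKO-D values lay above Ctrl-D values on the whole. Gene lists below were fixed before the data were examined, and a member is counted as higher or lower in Eed iKO-D when it differed at least 1.5 times. By this rule 7636 of all 19613 measured genes were higher and 3303 lower. The same counts were 4857 and 3903 of 17151 genes in fibroblast-like and 4024 and 2843 of 11004 in neutrophil-like cells. In T cell-like cells they were 1704 and 2040 of 9476. Counts of list members are to be read against these. Class values mix clusters that the libraries held in different numbers. Cells with follicle and pigment genes were mostly Ctrl-D. Cluster 8, whose leading genes include Krt15 and Lhx2, held 1612 Ctrl-D and 85 Eed iKO-D cells. The hair keratin cluster outside the class held 504 and 4, and melanocyte-like cells numbered 248 and 7. Class ratios may therefore partly compare different skin tissue in the libraries, which cannot be told apart from genotype here. Among the single genes named here, Ezh2, Flg, Ivl, Krt10, Krt1, Krt15, Krt5, Mmp10, Spry4, Inhba, Sox11, Cdkn2b, Krt19, Krt7, Cd274, H19 and Lgr5 were each at least 1.5 times higher in some of the 5 shared clusters and at least 1.5 times lower in others, so no single direction is read from them. The Ctrl-D values of Pitx1, Krt18, Stra6, Cdkn2a and Vim came mostly from cluster 2, which held Ctrl-D cells only. Of its cells, 21 had UMIs of Xist only, an RNA of female cells, and 275 of Y-linked genes only. Ctrl-D cells of cluster 7 had 164 and 1. Clusters may thus also stand for sex, animals or tumours, and ratios within shared clusters are not matched for sex.

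Over the whole class, 18 of 24 cornified envelope genes were lower in Eed iKO-D and 1 was higher, with a median log2 ratio of −2.23. Within shared clusters the medians ran from −3.04 in cluster 1 to 0.38 in cluster 8, and the median was 0.68 among basal-like clusters alone. Lor, the main protein of the cornified envelope, stood at 405 CPM in Ctrl-D and 18.7 in Eed iKO-D (ratio 0.0461). Flg, whose product bundles keratin filaments, stood at 139 and 19.8 CPM over the class but at 1243 and 1914 CPM within cluster 11, and Ivl, another envelope precursor, at 20.5 and 19.9. Krt10, the keratin of spinous cells, had a ratio of 0.191 (816 against 156 CPM), and its partner Krt1 a ratio of 0.292 (712 against 208 CPM). Within clusters the direction of both turned. Krt10 was higher in Eed iKO-D in clusters 0 (628 against 1746 CPM), 6 (27.4 against 94.5 CPM) and 11 (4334 against 8215 CPM), and lower in clusters 1, 7 and 8. Krt1 was likewise higher in clusters 0, 6 and 11 (2506 against 4403 CPM in the last) and lower in the other 3. Of 13 spinous genes, 7 were lower and 4 higher (median −0.87), but the median was 1.01 in cluster 0 and −1.18 in cluster 1. The late cornified envelope genes Lce1b (169 CPM in Ctrl-D), Lce1a1 (167), Lce1d (131) and Lce1a2 (151) were each below 0.2 CPM in Eed iKO-D. Lce1a2 had 1 UMI there, a ratio of 4.75e-05 (1.2e-06 to 0.000265). Lce1m stood at 204 and 2.47 CPM. Lce1c and Lce1l had 0 UMIs in Eed iKO-D and were at least 3048-fold and 2960-fold lower, against a floor of 3 UMIs in the class. The Lce1 genes are near-identical neighbours on chromosome 3, so the division of reads among them is uncertain. Over 99% of the Ctrl-D UMIs of Lce1b, Lce1a1, Lce1a2, Lce1m, Lce1d, Lce1c and Lce1l came from cluster 11, with 562 Ctrl-D and 32 Eed iKO-D cells. Fewer cells there do not account for Lce1a2 or Lce1c: at the Ctrl-D level those 32 cells would have held 1266 and 548 UMIs of them, and they held 0 of each. For Lce1m they would have held 1714 UMIs and held 343, so fewer cells account for most of its class difference. Lor stood at 3666 and 2740 CPM within cluster 11, so its class value follows the number of such cells more closely.

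Other genes lowest in Eed iKO-D were Cck, Ccl27a, Defb6 and Crct1. Cck, which encodes the peptide cholecystokinin, stood at 386 and 0.287 CPM, a 1347-fold difference, and 98.3% of its Ctrl-D UMIs came from cluster 2, which held Ctrl-D cells only. Ccl27a, a keratinocyte chemokine that attracts skin-homing T cells, stood at 369 and 14.1 CPM (ratio 0.0382). Its symbol is carried by more than 1 gene ID, so its level is uncertain. Defb6, a beta-defensin, stood at 343 and 16.6 CPM, with 95.2% of its Ctrl-D UMIs in cluster 11. Within that cluster it stood at 2990 and 2204 CPM, so its class value mostly follows the number of such cells. Crct1, a gene of the epidermal differentiation region, stood at 255 and 14.5 CPM.

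Of 13 basal keratinocyte genes, 8 were higher in Eed iKO-D and 1 lower (median log2 ratio 1.20). This value depended on the mix of clusters: it was 0.084 in suprabasal-like clusters alone and ran from −0.032 in cluster 0 to 1.34 in cluster 1. Itgb4 and Itga6, the integrins of the hemidesmosome, were 3.91-fold (106 against 416 CPM) and 2.57-fold (366 against 939 CPM) higher, Itga6 at least 1.5-fold in only 1 of 5 shared clusters. Krt15, a keratin of resting basal cells and a leading gene of cluster 8, which was mostly Ctrl-D, stood at 644 and 85.3 CPM, with ratios from 0.487 to 2.66 within shared clusters. Krt5 (5182 against 5749 CPM), Krt14 (13657 against 15887 CPM) and Trp63, the master regulator of stratified epithelium (274 against 438 CPM), had ratios of 1.11, 1.16 and 1.60. The wound keratin Krt6a was 2.30-fold higher (1991 against 4588 CPM), but within no shared cluster did it differ 1.5-fold, and in clusters 1 and 8 it was slightly lower. Of 24 invasion and matrix remodelling genes, 20 were higher and 3 lower (median 1.47). Examples were Lama3, a chain of laminin-332 (136 against 971 CPM, 7.13-fold), Pdpn, a glycoprotein of invading edges (21.3 against 151 CPM, 7.09-fold), and the protease Mmp10 (16.3 against 143 CPM, 8.79-fold). Of 14 squamous tumour stem cell genes, 12 were higher and 1 lower (median 1.67), among them Cd44 (416 against 1410 CPM, 3.39-fold). Within shared clusters the invasion median was 0.35. It stood clearly above the median of all genes in cluster 1 (1.22 against 0.75) and cluster 8 (1.23 against 0.28) and near it in clusters 0, 6 and 7, so the class value of this list rests largely on which clusters each library held. The stem cell median within shared clusters was 0.91 and lay above the median of all genes in each of the 5. Lama3, Itgb4 and Hmga2 are among the genes that define cluster 7.

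Of 25 outputs of the Ras-MAPK pathway, 19 were higher and 3 lower, with a median log2 ratio of 0.95 and 0.55 within shared clusters. In cluster 1 the list lay below the median of all genes (0.39 against 0.75), and in cluster 7 it was close to it (0.55 against 0.42). Hmga2, a chromatin protein of embryonic and tumour cells, was 7.63-fold higher (33.0 against 252 CPM). Cluster 2 held 49.3% of its Ctrl-D UMIs, and without that cluster it stood at 18.6 and 252 CPM. Its ratios within shared clusters ran from 1.25 in cluster 6 to 7.47 in cluster 1. The EGF receptor ligands Areg (302 against 962 CPM, 3.19-fold) and Ereg (67.8 against 179 CPM, 2.64-fold) and the feedback phosphatase gene Dusp6 (75.7 against 136 CPM, 1.79-fold) were higher, Dusp6 within all 5 shared clusters but Areg at least 1.5-fold in only 1 of them and Ereg in 2. Without cluster 2, Ereg stood at 37.3 and 179 CPM. The feedback inhibitor Spry4 stood at 1.26 and 0.674 CPM and went both ways within shared clusters.

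Of 26 hypoxia and glycolysis genes, 22 were higher and none lower (median log2 ratio 1.60, and 0.66 within shared clusters). Ndrg1, a stress gene of low oxygen, was 5.53-fold higher (148 against 817 CPM), Bnip3, a mitophagy receptor, 3.86-fold (31.7 against 122 CPM) and lactate dehydrogenase Ldha 1.62-fold (699 against 1136 CPM), but Ldha by 1.5-fold in none of the 5 shared clusters and Bnip3 in 2. Vegfa, the main angiogenic growth factor, stood at 71.1 and 332 CPM, 4.66-fold (4.55 to 4.78) higher. Of 36 growth factors and angiogenic ligands, 21 were higher and 7 lower (median 1.17, and 0.089 in suprabasal-like clusters alone). Among them Inhba, which encodes activin A, stood at 22.5 and 114 CPM but was not higher in Eed iKO-D within clusters 6, 7 and 8 (0.447-fold in cluster 7), and the growth factor Ptn, a leading gene of cluster 8, at 174 and 22.4 CPM.

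The genes highest in Eed iKO-D by the preset rule included Arg1, Prl8a9, Fabp4, Slc25a21, Stra6, Spon2, Ptprz1, Adm, Wnt5a, Igf2bp2 and Ly6k. Arg1, the arginase that consumes arginine, stood at 2.65 and 247 CPM, 93.3-fold (82.7 to 106) higher. Prl8a9, of the placental prolactin family, stood at 1.99 and 126 CPM, and 92.6% of its Eed iKO-D UMIs came from cluster 7. Fabp4, a fatty acid carrier, was 17.2-fold higher (38.7 against 667 CPM), and the retinol transporter Stra6 28.1-fold (3.63 against 102 CPM). Adm, which encodes the vasodilator adrenomedullin, was 18.1-fold higher (4.65 against 84.3 CPM), and the Wnt ligand Wnt5a 9.14-fold (31.4 against 287 CPM). Further ratios were 24.3 for Slc25a21, 31.2 for Spon2, 11.6 for Ptprz1, 8.97 for the RNA-binding protein gene Igf2bp2 and 18.5 for Ly6k. Arg1, Prl8a9 and Slc25a21 lead clusters 25 and 7, which were mostly Eed iKO-D, so their class values partly restate the clustering. Of the 24 genes chosen by the rule, 15 differed at least 1.5 times in the same direction within all 5 shared clusters. In clusters that do not make cornified envelope genes such values can come from free RNA. The 24 genes were picked for extreme ratios in the same cells, so agreement within clusters is partly built in. The share of all genes that meet this criterion was not computed.

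Hox genes, which PRC2 is known to repress, were lower in Eed iKO-D epithelial-like cells. Of 25 measured, 19 were lower and none higher (median log2 ratio −1.17, 0th percentile among 10000 random lists matched on expression, as a description of these libraries). Hoxa9 stood at 6.14 and 0.588 CPM, Hoxc8 at 28.6 and 6.43, Hoxb8 at 12.1 and 3.03, and Hoxc13, a regulator of hair keratins, at 7.01 and 1.29. Within shared clusters the medians lay between −1.10 and −0.36. Developmental transcription factors of other lineages went both ways, with 26 of 48 higher and 16 lower (median 0.88, 0.36 for the 26 members that passed the guard against free RNA, and −0.48 after 10% of the UMIs were subtracted with the profile of the whole library). Pax9 (2.38 against 20.4 CPM, 8.58-fold), Sox11 (0.799 against 7.50 CPM, 9.39-fold) and Pitx1 (37.4 against 115 CPM, 3.08-fold) were higher over the class. Sox11 was higher in only 2 of 5 shared clusters, while Pitx1 was higher in all 5 and stood at 6.93 and 115 CPM without cluster 2. Lhx2 and Tbx1, transcription factors of hair follicle stem cells and leading genes of cluster 8, were lower, at 17.9 and 0.681 CPM and at 19.7 and 2.44 CPM. Cdkn2a, a classic PRC2 target that encodes p16 and p19Arf, stood at 75.6 and 82.0 CPM, and its neighbour Cdkn2b at 24.4 and 34.9 CPM (ratios 1.08 and 1.43). The near-equal class value of Cdkn2a hides a difference in clusters: 61.6% of its Ctrl-D UMIs came from cluster 2, and without that cluster it stood at 32.3 and 82.0 CPM, 2.54-fold higher in Eed iKO-D. That comparison kept cluster 25, with 5 Ctrl-D and 380 Eed iKO-D cells, where Cdkn2a stood at 226 CPM in Eed iKO-D. Within each shared cluster it differed by less than 1.5-fold. Its ratio was 1.39 in cluster 1 but 0.680, 0.700, 0.912 and 0.684 in clusters 0, 6, 7 and 8. No rise of Cdkn2a is therefore read from the 2.54-fold value. Sox2 had 1 UMI in Ctrl-D and 7 in Eed iKO-D, a ratio of 5.02 (0.645 to 226), and the Merkel cell factor Isl1 had 11 and 24 UMIs, a ratio of 1.57 (0.738 to 3.54).

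Of 5 simple epithelial keratins, 3 were higher and 2 lower over the class. The mix of clusters may have given only part of this. In clusters 1 and 7 all 4 measured there were higher, but Krt7 was lower in the other 3 shared clusters, at 0.175-fold in cluster 0, 0.0908-fold in cluster 6 and 0.612-fold in cluster 8. The ratios in clusters 1 and 7 rest on few Ctrl-D UMIs. Krt8 stood at 0.352 and Krt18 at 2.11 CPM in the 107 Ctrl-D cells of cluster 1. Krt8 stood at 1.87 CPM in the 167 Ctrl-D cells of cluster 7. Krt8 was 10.2-fold higher (0.699 against 7.16 CPM, interval 8.03 to 13.2), Krt18 3.25-fold (6.58 against 21.4 CPM) and Krt19 1.85-fold (1.28 against 2.37 CPM), while Krt7 had a ratio of 0.106 (9.43 against 0.996 CPM). The mesenchymal filament gene Vim stood at 71.0 and 35.8 CPM (ratio 0.504), but most of its Ctrl-D UMIs came from cluster 2, which held Ctrl-D cells only. Without that cluster Vim stood at 7.86 and 35.8 CPM, 4.55-fold higher in Eed iKO-D, at levels that free RNA could supply. Of 24 genes of epithelial-mesenchymal transition (EMT), 15 were higher and 6 lower (median log2 ratio 1.20), but only 3 of these genes passed the guard against free RNA. Col1a1, a fibroblast collagen, was at 0.0350% of its fibroblast level in Ctrl-D epithelial-like cells and at 0.743% in Eed iKO-D. Subtraction of 10% of the UMIs with the profile of the whole library gave an EMT median of −3.86, and other clusterings gave 2.28 and 2.33. Of 20 epithelial junction and identity genes, 10 were higher and 1 lower (median 0.58).

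Over the whole class the medians were −0.09 for 42 S phase genes and 0.05 for 52 G2/M genes, but clusters went opposite ways. The S phase median was −0.97 in cluster 8 (none higher, 32 lower) and 1.10 in cluster 1 (33 higher, none lower), and the G2/M median −0.38 and 0.81 there. The median of all genes in cluster 1, given above, was itself high. The G2/M value there was close to it, and the S phase value lay only moderately above it. Of single genes, Mki67 stood at 138 and 164 CPM. After each cell was thinned to 1500 UMIs, 15.3% (14.4 to 16.3; 5329 cells, 107 left out) of Ctrl-D and 8.08% (7.14 to 9.08; 3133 cells, 12 left out) of Eed iKO-D epithelial-like cells passed the limit for cycling. Without thinning the shares were 14.4% and 5.98%. With each cell assigned by its own marker UMIs the Eed iKO-D share was 2.16%. Random lists matched on expression had a median of 0.28 for both lists, and the S phase and G2/M medians lay at percentiles 0.4 and 3.82 among them. Both lists were thus low against matched genes, as was the cycling share, while Mki67 was slightly higher. Because clusters went opposite ways, no order is read from these values.

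**Figure D2:**
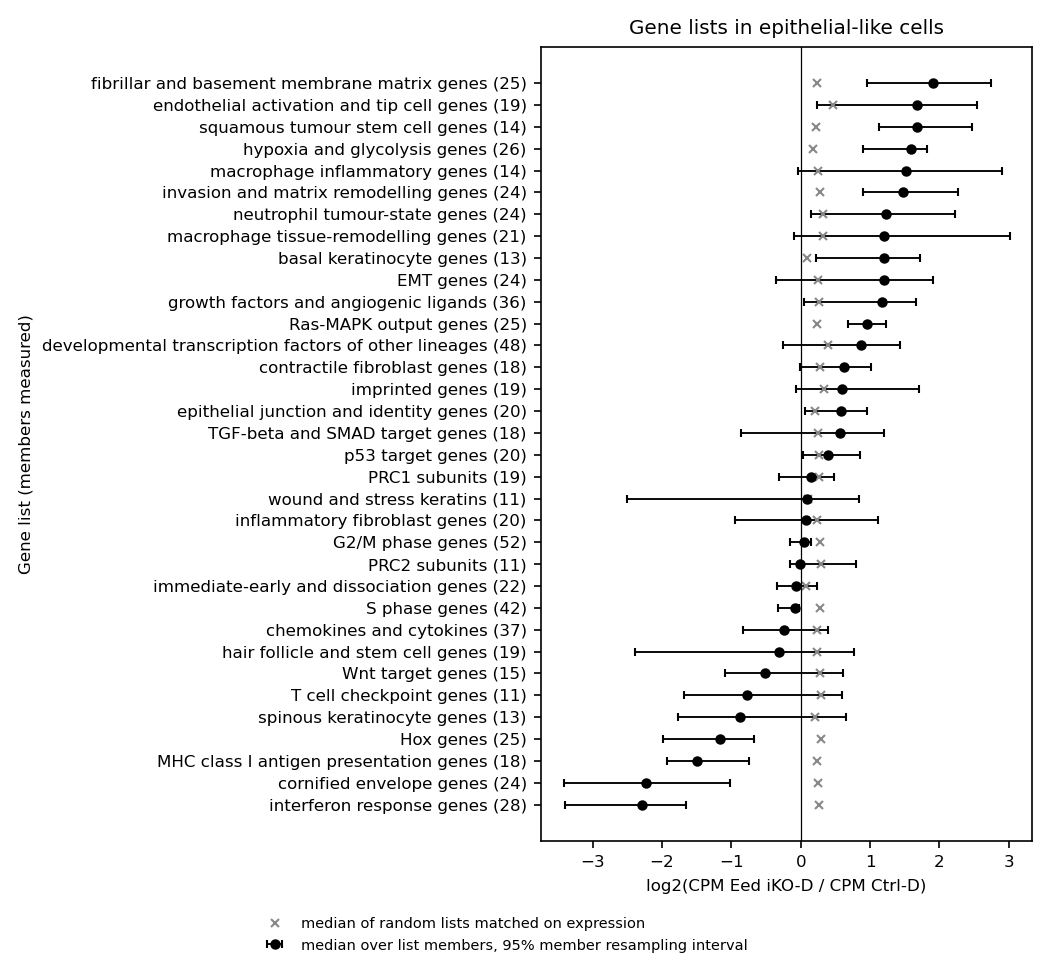
Median log2 ratio (Eed iKO-D over Ctrl-D, CPM) in epithelial-like cells for each gene list with at least 10 measured members. Points are medians with 95% intervals from resampling members, and crosses are medians of random lists matched on expression; Hox genes (−1.17) and interferon response genes (−2.29) lie left of 0, hypoxia and glycolysis genes (1.60) right of it.

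Interferon response genes were lower in Eed iKO-D in epithelial-like, fibroblast-like, neutrophil-like and T cell-like cells. In epithelial-like cells 23 of 28 were lower and 1 was higher (median log2 ratio −2.29). The antiviral gene Isg15 stood at 78.7 and 3.58 CPM, Ifi27l2a at 204 and 3.67, the chemokine gene Cxcl10 at 51.0 and 3.33, and Irf9, part of the interferon signalling complex, at 28.0 and 6.48. The first 3 of these were high enough in other classes for free RNA to contribute, and the 4 members clear of that had a median of −1.40. With each cell assigned by its own marker UMIs the list median was −1.54. MHC class I genes were lower too: 13 of 18 were lower and none higher (median −1.49, and −0.38 within shared clusters). B2m, the light chain of MHC class I, stood at 1409 and 333 CPM, and the immunoproteasome subunit Psmb9 at 134 and 12.4 CPM. Cd274, which encodes the checkpoint ligand PD-L1, stood at 8.72 and 3.97 CPM. Cluster 2, with 632 of the 5436 Ctrl-D cells, held 36.4% of its Ctrl-D UMIs, more than evenly spread free RNA would give. Without that cluster Cd274 stood at 6.16 and 3.97 CPM, levels that free RNA of neutrophils could supply.

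Both libraries held cells with reads of Xist, the RNA of the inactive X of female cells, and cells with reads of Y-linked genes. Of named cells, 47.4% in Ctrl-D and 58.7% in Eed iKO-D had Xist UMIs only, and 28.1% and 14.8% had Y gene UMIs only. The interferon difference was not alike in both kinds of epithelial-like cells. The median was −3.54 in Xist-only cells (2701 Ctrl-D and 1779 Eed iKO-D) and −0.48 in Y-only cells (1590 and 480). The list summed to 1147 CPM in Xist-only and 376 CPM in Y-only Ctrl-D cells, and to 120 and 243 CPM in Eed iKO-D. Hox genes also differed in this way, with medians of −1.78 in Xist-only and −0.17 in Y-only cells. The 2 kinds of Ctrl-D cells lay in different clusters, with 164 Xist-only and 1 Y-only in cluster 7 and 21 and 275 in cluster 2. The split therefore also compares different mixes of clusters. In the Y-only cells of other classes the list stood at 1641 and 772 CPM (fibroblast-like), 2290 and 686 CPM (neutrophil-like) and 1636 and 1014 CPM (T cell-like; Ctrl-D, then Eed iKO-D). Xist-only cells were lower as well in fibroblast-like and T cell-like cells (2752 against 870 CPM and 2695 against 1050 CPM), and were too few in Ctrl-D neutrophil-like cells. Hypoxia and glycolysis genes had medians of 1.58 and 1.13, Ras-MAPK genes 0.89 and 1.17, invasion genes 1.71 and 1.58, and cornified envelope genes −2.21 and −2.97.

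**Figure D3:**
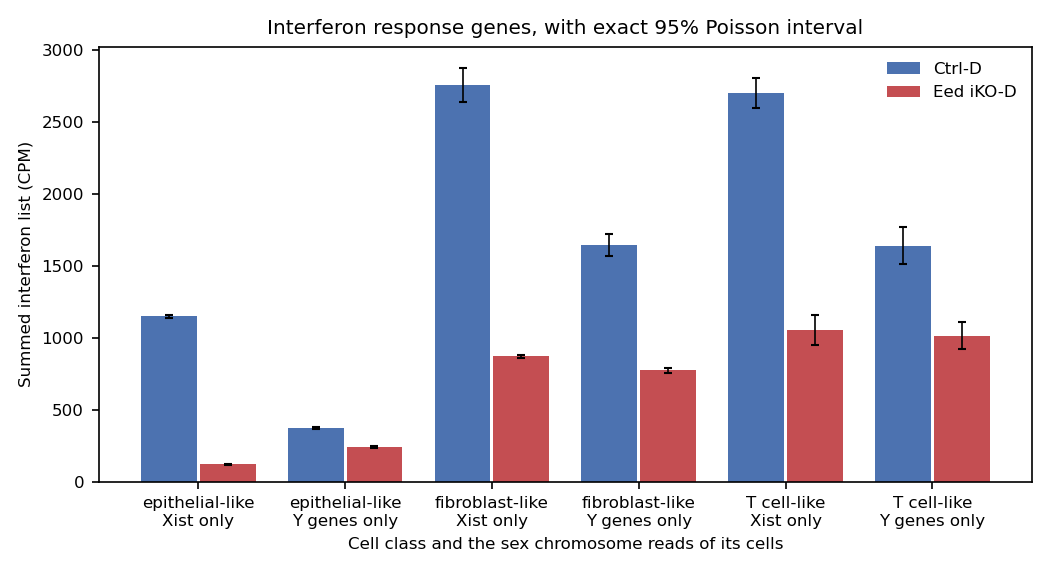
Summed CPM of interferon response genes in cells with Xist UMIs only and with Y gene UMIs only, for 3 cell classes, in Ctrl-D (blue) and Eed iKO-D (red), with exact 95% Poisson intervals. In epithelial-like cells the Ctrl-D bars stand at 1147 and 376 CPM and the Eed iKO-D bars at 120 and 243 CPM.

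In fibroblast-like cells (248 in Ctrl-D and 2440 in Eed iKO-D), contractile genes were higher and inflammatory genes lower in Eed iKO-D. Clusters 4 and 22 formed the class, and 208 of the Ctrl-D cells lay in cluster 4 but 1550 of the Eed iKO-D cells in cluster 22. Of 18 contractile genes, 15 were higher and none lower (median log2 ratio 1.24). Acta2, the smooth muscle actin of myofibroblasts, stood at 160 and 582 CPM, the matrix glycoprotein gene Tnc at 600 and 2607 CPM, and the collagen gene Col12a1, a leading gene of cluster 22, at 954 and 3230 CPM. Acta2 was also high in pericyte-like cells, whose free RNA can add to it, and the contractile median was 0.56 with cells assigned by their own marker UMIs. Of 20 inflammatory fibroblast genes, 10 were lower and 3 higher (median −0.69), among them the chemokine genes Ccl11 (569 against 154 CPM) and Cxcl12 (531 against 252 CPM), while the acute-phase gene Saa3 was higher (835 against 1522 CPM). Of 29 interferon response genes, 22 were lower and none higher (median −1.13), and of 18 MHC class I genes 10 were lower and none higher (median −0.99, and −0.15 for the 8 members that passed the guard against free RNA). Hox genes had a median of −0.056, and of −0.48 for the 16 members that passed the same guard. The genes highest by the rule were Serpinb2, a protease inhibitor (3.49 against 357 CPM, 102-fold), Kcnma1 (22.5-fold), Dpp6 (30.4-fold) and the collagen gene Col11a1 (7.42 against 144 CPM, 19.3-fold). The lowest were the sphingomyelinase gene Smpd3 (313 against 9.87 CPM), Inmt (123 against 1.10 CPM), Myoc (131 against 3.97 CPM) and Mrgprg (67.7 against 0.445 CPM). In simulated data with these depths, 21.1% of unchanged genes passed 1.5-fold by counting error alone, so single ratios near that limit carry little weight.

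Neutrophil-like cells (137 and 1138, all in cluster 5) had 0 UMIs of Ngp, Camp, Csta2 and Prtn3 in Ctrl-D, where the class held few UMIs. Ngp, a neutrophil granule protein, was at 1011 CPM and at least 65.5-fold higher, Camp, the cathelicidin, at 711.5 CPM and at least 46.1-fold higher, and Prtn3, the azurophil protease, at 103 CPM and at least 6.67-fold higher. Csta2 was at 164 CPM, with a bound of 10.6 that paralogs make uncertain. Ltf, which encodes lactoferrin, stood at 20.6 and 416 CPM. Ngp and Camp are among the leading genes of cluster 5, which was mostly Eed iKO-D. Lower genes were H2-Q10 (535 against 44.8 CPM, uncertain among H2-Q paralogs), Isg15 (602 against 56.9 CPM), the adhesive glycoprotein gene Thbs1 (1728 against 227 CPM) and Crlf3 (283 against 41.8 CPM). Cd274 stood at 1250 and 379 CPM (ratio 0.303). Of 22 interferon response genes 17 were lower and 2 higher (median −1.37), and of 17 MHC class I genes 12 were lower and 2 higher (median −1.15). With each cell assigned by its own marker UMIs the interferon median was −0.65. Hypoxia and glycolysis genes were higher in 20 of 25 and lower in none (median 1.14), among them Bnip3 (30.9 against 128 CPM) and the glucose transporter Slc2a1 (108 against 307 CPM). The median of all genes was 0.17. Ctrl-D neutrophil-like cells had 194450 UMIs in all, and 41.1% of unchanged genes passed 1.5-fold by counting error alone at that depth in simulated data. Of the Ctrl-D cells, 5 had Xist UMIs only and 42 Y gene UMIs only, but 327 and 188 of the Eed iKO-D cells. Sex or animal may thus add to every ratio in this class.

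In T cell-like cells (470 and 154, all in cluster 12), Cd8a stood at 137 and 29.5 CPM, Cd8b1 at 193 and 37.4, and the cytotoxic granule gene Nkg7, a leading gene of the cluster, at 703.5 and 186. Gzmc stood at 82.2 and 863 CPM. Gzmf, Gzmd and Gzme had 0 UMIs in Ctrl-D and stood at 342, 241.5 and 145 CPM in Eed iKO-D, at least 214-fold, 151-fold and 90.6-fold higher. These granzyme genes are close paralogs, so the division of reads among them is uncertain. Of 13 cytotoxicity genes, 6 were lower and 3 higher (median log2 ratio −0.49). The fourth gene highest by the rule, Camk1d (498 against 13311 CPM), follows the ribosomal transcript described below. Among the lowest were the interferon-inducible gene Mndal (140 against 6.95 CPM), the cell cycle regulator Rgcc (320 against 35.6 CPM) and the histone gene Hist1h2ap (172 against 23.5 CPM). Of 21 interferon response genes 17 were lower and none higher (median −1.35), and of 18 MHC class I genes 9 were lower and 1 higher (median −0.60). Of 12 checkpoint genes 4 were lower and none higher (median −0.27), and of 10 regulatory T cell genes 4 were lower and 1 higher (median −0.41). Foxp3, the regulatory T cell factor, stood at 132 and 95.6 CPM. Macrophage-, endothelial- and pericyte-like cells had fewer than 100 cells in Ctrl-D, and melanocyte-, dendritic cell- and mast cell-like cells in at least 1 library, and were not compared.

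A transcript that overlaps ribosomal RNA differed between the libraries in every class. Gm42418 (ENSMUSG00000098178, mm10 chromosome 17, 39846958 to 39848788) took 0.515% of the UMIs of kept cells in Ctrl-D and 9.72% in Eed iKO-D. It was 7.17-fold higher in epithelial-like cells, 8.28-fold in fibroblast-like, 20.9-fold in neutrophil-like and 25.3-fold in T cell-like cells. In cells of the unnamed clusters it took 0.399% and 30.4%.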

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

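The tests in this part were chosen after the result they measure was seen, except the split of the interferon response genes by Xist and Y gene reads and the comparison of these genes with the level of the whole library, which were chosen after the pattern but before their own result was seen.

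Signals in clusters that no comparison used lay above the limit that a count of 0 allows, but their genes were picked for high values after these were seen, so that limit alone decides little. Acp5, an enzyme of osteoclasts and some macrophages, stood at 459 CPM in an unnamed cluster of 13 Ctrl-D and 676 Eed iKO-D cells, against a limit of 0.514 CPM, and at 251 CPM in macrophage- or monocyte-like Eed iKO-D cells. Krt25, a keratin of the hair follicle's inner root sheath, stood at 847 CPM in a cluster of 504 Ctrl-D and 4 Eed iKO-D cells (limit 0.407 CPM). Siglech, a marker of plasmacytoid dendritic cells, stood at 2341 CPM in a cluster of 24 and 28 cells (limit 6.29 CPM).

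Interferon response genes were lower in Eed iKO-D in all 4 compared classes. A different mix of epithelial-like clusters does not account for it, since the highest median within a shared cluster was still −1.15. Free RNA with the profile of the whole Ctrl-D library is argued against in fibroblast-, neutrophil- and T cell-like cells. At least 77.3% of measured members stood above the library level in each of them. Epithelial-like cells gave 100128612 of the 116482627 UMIs behind that level, so free RNA with another profile is not excluded. In epithelial-like cells this was not tested, and only 4 of 28 members passed the guard against free RNA. An effect limited to cells that express the Cre is argued against by the medians in the other 3 classes, of which the highest was −1.13. Different shares of male and female cells may explain part of it: the median within Y-only epithelial-like cells was −0.48, but it was −3.54 within Xist-only cells, which those shares alone cannot give. Single animals or tumours with a strong interferon response in Ctrl-D, which would need to include male cells because Y-only fibroblast-like cells stood at 1641 and 772 CPM, and an effect of Eed loss on the whole tumour both stay open as hypotheses.

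Hox genes were lower in epithelial-like cells of Eed iKO-D, opposite to the direction that loss of PRC2 repression would give. Skin from another body position was set against the Hox median of fibroblast-like cells. That median was −0.056, and −0.48 for members that passed the guard against free RNA. It cannot decide the question. Of 28 members there, 5 were higher and 9 lower, so a median can hide moves in both directions. Most Ctrl-D cells of that class lay in cluster 4 and most Eed iKO-D cells in cluster 22. Body position thus stays open. The mix of clusters is not settled, since the medians within shared clusters kept the sign but reached only −0.36. Different shares of male and female cells could give part of the difference, with a median of −0.17 in Y-only cells, but not the part in Xist-only cells, at −1.78. Few animals or tumours in each library, and an indirect effect of Eed loss on follicle-derived cells, stay open and were not tested.

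Gm42418, a transcript over ribosomal RNA, was higher in every class of Eed iKO-D. Barcodes with few UMIs do not account for it, since the ratio was 7.83 among epithelial-like cells with at least 10000 UMIs. The lowest ratio among the other classes was 7.39, but this cannot exclude a change limited to Cre-expressing cells, because free RNA can carry Gm42418 between classes. In the unnamed Eed iKO-D clusters 10 and 27 it took 41.5% and 39.3% of UMIs, with Krt14 at 10374 and 11108 CPM. A difference in RNA or library preparation over the whole library is consistent with the lowest ratio of 7.17 over all named classes. No other biological explanation was tested.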

How the results depend on the processing

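Settings without Gm42418, by Xist or Y gene reads, within shared clusters, by the free RNA guard, without the top 8% of doublet scores, and with or without single clusters were chosen after the data were seen, although for interferon genes the split by Xist or Y gene reads was chosen before its own result was seen; the others were planned. Of the main results, 414 recalculated values stayed within the interval of the main value, 65 moved beyond it and 2 reversed; of the lesser results 20 stayed and 8 moved. Except where the setting itself names it, the cause was not tested. Depth limits neutrophil-like cells most, and cells added by the looser filter had no doublet call. No paired analysis was possible because each group had 1 library.

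Medians are log2 ratios in epithelial-like cells unless another class is named, and shares are of epithelial-like cells among named cells (Ctrl-D, then Eed iKO-D). The reversals were Eed at 0.039 within shared clusters and the cornified envelope median at 0.68 in basal-like clusters, where the PRC2 median was −0.20. Within shared clusters the medians were also 2.20 for EMT, −0.65 for Hox, −0.38 for MHC class I, 0.55 for Ras-MAPK, −0.30 for cornified envelope, 0.66 for hypoxia, 0.35 for invasion and 0.91 for stem cell genes. In suprabasal-like clusters they were 0.45 for Ras-MAPK, 0.084 for basal, −0.75 for cornified envelope and 0.45 for invasion genes. In Xist-only cells Eed was −0.27, Ink4/Arf and Cdk inhibitors 0.51, PRC2 −0.18 and interferon −3.54; in Y-only cells Hox was −0.17 and interferon −0.48.

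With classes assigned per cell, Eed was −0.32, EMT 2.21, interferon −1.54, contractile genes in fibroblast-like cells 0.56, hypoxia and interferon in neutrophil-like cells 0.57 and −0.65, cycling shares 17.2% and 2.16%, and the Eed iKO-D share 75.0%. Clustering at resolution 0.5 gave EMT 2.28, contractile 0.64 and shares of 76.9% and 32.9%, and at 1.5 EMT 2.33 and shares of 78.5% and 29.0%. With doublets kept, EMT was 2.29, MHC class I and hypoxia in neutrophil-like cells −1.60 and 0.62, and the Ctrl-D share 77.6%. Without the top 8% of doublet scores, EMT was 2.48, contractile 0.54 and shares 77.6% and 31.7%. The stricter cell filter gave EMT 2.35 and an Eed iKO-D share of 33.5%, and the looser one shares of 79.0% and 36.8%. With the hair keratin cluster, the Ctrl-D cycling share was 17.5% and the Ctrl-D share 82.0%; without the cluster led by Cck and H19, EMT was 2.29 and the Ctrl-D share 78.6%.

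Subtraction of 10% free RNA gave EMT −3.86, developmental factors −0.48 and interferon −3.89; the first 2 changed sign, but their main intervals included 0. With guarded members only, interferon was −1.40, and −0.85 in T cell-like and −1.26 in fibroblast-like cells. Centring on the median of all genes gave Eed −0.50, PRC2 −0.35 and Ras-MAPK 0.61. Without the 50 genes with most UMIs Eed was −0.21. Without Gm42418 and genes that follow it, Eed was −0.11, MHC class I in T cell-like cells −0.31 and hypoxia in neutrophil-like cells 1.51. Without thinning, the Eed iKO-D cycling share was 5.98%.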

Other observations

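Imprinted genes in epithelial-like cells went both ways, with 10 of 19 at least 1.5 times higher in Eed iKO-D and 5 lower (median log2 ratio 0.59). Among random lists matched on expression, whose median was 0.33, this lay at percentile 84.4. Airn, the antisense RNA of the Igf2r locus, stood at 39.9 and 172 CPM (4.33-fold), and the growth-restricting RNA H19 at 38.2 and 7.31 CPM. Of the Ctrl-D UMIs of H19, 89.1% lay in cluster 2, which held Ctrl-D cells only. Without that cluster H19 stood at 4.62 and 7.31 CPM. Within shared clusters it was at least 1.5 times higher in 2 and lower in 3, so no direction is read from it. Airn and Igf2r overlap, so their reads are uncertain. Of 19 hair follicle and stem cell genes, 9 were lower and 6 higher (median −0.31), and the follicle stem cell receptor Lgr5 stood at 41.1 and 3.78 CPM. Lgr5 was not lower within cluster 8 (155 against 239 CPM), which held 1612 Ctrl-D and 85 Eed iKO-D cells, and the list median there was 0.54. Of 20 p53 target genes 10 were higher and 2 lower (median 0.40), and of 18 TGF-beta and SMAD target genes 9 were higher and 5 lower (median 0.57). Among matched random lists, with medians of 0.26 and 0.24, these lay at percentiles 74.8 and 94.05, inside the spread of such lists. Of 22 immediate-early and dissociation genes, 3 were higher and 4 lower (median −0.06). Fibrillar and basement membrane matrix genes had a median of 1.91, but 1 of 25 passed the guard against free RNA.

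Hypoxia and glycolysis genes were also higher in fibroblast-like cells (14 of 26, none lower, median 0.92, although only 8 members passed the guard against free RNA, 4 of them higher) and near 0 in T cell-like cells (7 of 25 higher, 1 lower, median −0.02). In fibroblast-like cells the list of Ink4/Arf and Cdk inhibitors had 0 members higher and 2 of 7 lower, and Cdkn2a stood at 67.2 and 19.6 CPM there.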
